A study of Sus scrofa with 16 samples.

How the data were processed

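The data were expression values of 2 skeletal muscles, diaphragm and psoas major (a loin muscle beside the lumbar spine), from 8 Iberian pigs slaughtered at 211 days of age. There were 4 males and 4 females, and in each sex 2 animals on the high feeding level and 2 under 20% feed restriction. Whether the males were castrated and when the restriction began are not given in the sources used here, so that differences by sex and feeding hold for the groups as the labels name them. Each animal gave 1 array per muscle, so that 16 Affymetrix porcine arrays made up 8 combinations of muscle, sex and feeding level with 2 arrays each. Muscles were kept at low temperature, and total RNA was isolated with a kit and converted to biotinylated cRNA, per the labels' protocols.

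The values used were the log2 expression values that the authors deposited, 1 value per probe set and array. Their summary method was GCRMA per the submitters' processing notes. Its version, and whether all 16 arrays were processed together, are not given in the sources used here. GCRMA corrects background from probe sequence, makes the distributions of arrays processed together equal and summarises the probes of a set, so that a shift shared by most genes of an array is removed and values near the floor are compressed. The table held 24123 probe sets, and the deposited log2 values were used without further scaling. Median values per array lay between 3.56 and 3.62 and maxima between 15.7 and 15.9, and the most abundant muscle transcripts lay close to that upper end, where differences can be compressed. The precision was limited by the number of arrays.

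Gene names came from the platform annotation given for the table. Of the probe sets, 10099 had 1 gene symbol, 198 had several and 13826 had none, and no symbol changed when updated through gene identifiers of assembly Sscrofa11.1. Probe sets with several symbols were named as none of them. Where a gene had several tested probe sets, the one with the highest mean over all arrays stood for the gene. Of 979 such genes, 3 had probe sets called in opposite directions between the muscles.

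Probe sets were tested if their log2 value was at or above 4 in at least 4 of the 16 arrays. The 124 control probe sets were left out of tests and used as signs of RNA quality. This left 11467 probe sets, of which 5830 had 1 symbol, for 4571 genes. Tests used lmFit and eBayes of limma 3.58.1 in R 4.3.3 with Benjamini-Hochberg adjustment, and a probe set was called at an adjusted p under 0.05. Every adjusted p in the text for a probe set or gene is limma's, over all tested probe sets unless stated otherwise. Muscles were compared on all 16 arrays with sex and feeding level as covariates. Sexes and feeding levels were compared on 8 animals, each the mean of its 2 arrays, with the other factor as covariate, since an animal is 1 replicate. The same contrasts were fitted within each muscle on 8 arrays. Whether the muscle difference depended on sex or feeding level was tested on each animal's psoas minus diaphragm difference, and whether the feeding difference depended on sex was tested on the animal means, with 2 animals per combination.

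The animal numbers in the labels pair the arrays across muscles. After removal of the fitted effects, the 2 arrays of an animal correlated at 0.197, 0.0770, 0.110, 0.142, 0.0724, 0.208, 0.106 and 0.257 over probe sets in animals 1 to 8. All 8 were positive. In 7 of the 8 animals, animal 8 being the exception, the diaphragm array correlated more with the psoas array of at least 1 other animal. This sets 1 value against the highest of several, so that it cannot decide on the pairing, which is taken from the labels. A fit with the animal as a block was run as an alternative. No 2 arrays held identical values, and correlations between arrays of 1 muscle lay between 0.956 and 0.987.

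For gene lists, camera was run with a preset correlation of 0.01 on 1 probe set per gene, with adjustment over the lists of a comparison that had at least 3 tested genes. Camera with an estimated correlation and fry were run beside it. The 26 lists were slow and fast fibre genes, calcium handling, glycolysis and glycogen, the tricarboxylic acid cycle, oxidative phosphorylation, fatty acid oxidation, adipocyte and lipogenesis genes, cholesterol synthesis, axial patterning, extracellular matrix, growth and myogenic genes, protein breakdown, circadian, immediate early and stress genes, Y-linked and X-linked genes, sex steroid response, and markers of mesothelial cells, hepatocytes, erythrocytes, endothelium, smooth muscle, immune cells, Schwann cells and nerve, and fibroblasts. The lists, the tests and the rule for named genes were fixed before the data were examined. The rule took, per main comparison and direction, the 12 genes with the largest change among those called, with 1 symbol and the same sign in 8 of 8 animals (muscle) or groups that did not overlap after the covariate was subtracted (sex and feeding). With fewer than 5 such genes it added the 5 genes of smallest p in each direction. Up to 4 members of smallest p were taken per list, and up to 5 genes of smallest p in the other fits. Where every array of the lower group lay below 4, the change is given as at least N-fold, the higher group's mean against 4.

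Alternatives were no filter, a stricter filter of 6, quantile normalization, centring of each array, eBayes with trend and robust settings, array weights, the animal block, omission of the other factor, omission of each animal in turn and, for lists, the mean of a gene's probe sets. Alternatives that used the actin 3' minus 5' difference or the grouping of animals 1, 2, 3 and 5 as a covariate, and a fit on animals 4, 6, 7 and 8, were chosen after seeing the data. The fits were tested on simulated data with the residual spread of the real probe sets, with 50 changed probe sets of each size among 11467. The sizes were 1.5-, 2-, 4- and 8-fold. Probe sets were drawn independently of each other, so that the shares may be lower where genes move together or few of them change. For the muscle comparison, 74% of changes of 1.5-fold and 94% of changes of 2-fold were recovered. For sex these shares were 36% and 92%, and for feeding level 46% and 92%. For the dependence of the muscle difference on sex, 6% of 1.5-fold and 44% of 2-fold changes were recovered. Raw array scans were not used here.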

Results

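Expression was measured in the diaphragm, the main breathing muscle, and in the psoas major of 8 Iberian pigs of 211 days of age. Iberian pigs are a fat Mediterranean breed. The design compared the 2 muscles, males with females, and a high feeding level with 20% restriction, and each of the 8 combinations held 2 arrays. Between 11025 and 11163 probe sets per array had a log2 value at or above 4. The first principal component held 32.0% of the variance and separated the muscles.

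Among the called genes with the largest differences between the muscles were homeobox genes, a fast myosin, a calcium channel and albumin. HOXA9, a homeobox gene of posterior body position, was 16.4-fold higher in psoas than in diaphragm (log2 difference 4.03 ± 0.26 SE, adjusted p = 8.0e-08, n = 8 animals). MYH2, the myosin heavy chain of fast oxidative fibres, was 6.69-fold higher in psoas, at 15.26 ± 0.18 against 12.52 ± 0.39 (log2 mean ± SD, n = 8 arrays each). MEIS2, a homeobox cofactor of HOX proteins, was at least 26.1-fold higher in diaphragm, where it measured 8.71 ± 0.22 (SD, n = 8), while every psoas array lay below 4. RYR3, a calcium release channel, was lower in psoas by a log2 difference of -3.63 ± 0.23 (SE), with a psoas mean of 3.52, below 4, and ALB, the albumin gene of liver, was at least 13.3-fold higher in diaphragm with wide spread between animals (7.73 ± 1.80, SD, n = 8).

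In all, 3094 of 11467 probe sets passed the threshold, 1670 higher in psoas and 1424 higher in diaphragm. With 1 probe set per gene these were 793 and 556 of 4571 genes. Changes of 2-fold or more made up 120 and 190 probe sets. The genes named in this and the preceding paragraph differed in the same direction in 8 of 8 animals. On the psoas side were also PEG10, an imprinted gene derived from a retrotransposon (at least 3.20-fold, with every diaphragm array below 4), LOC100154873, which has no gene name in the annotation (log2 difference 2.29), and CNN1, a calponin of smooth muscle (2.08). HOXD8 (2.03), DKK2, a secreted Wnt regulator (1.94), FNTB, a farnesyltransferase subunit (1.88), PERP (1.76), ASNS, asparagine synthetase (1.75), and SH3BGR (1.64) followed. DKK2 had another tested probe set with the opposite sign. On the diaphragm side were TSPAN12 (log2 difference -2.68), FHL2, a LIM-domain protein of striated muscle (-2.53), RFLNA (-2.50), the adaptor SH3KBP1 (-2.49), the fructose transporter SLC2A5 (-2.31), ABLIM1 (-2.28), FIBIN (-2.07) and the Wnt regulator DKK3 (-2.03). The psoas means of RFLNA (3.90), SLC2A5 (3.99) and DKK3 (3.90) lay below 4, so that the sizes of these differences, like that of RYR3, rest in part on values near background. APOC3, an apolipoprotein of liver, was at least 2.79-fold higher in diaphragm. Of the 24 genes that the rule gave, 1 of which is not described here, 21 passed the threshold under every alternative tried, and FNTB (adjusted p = 0.131) and ASNS (0.0754) failed only with animals 4, 6, 7 and 8 alone. SLC2A5 did not pass with no filter (adjusted p = 0.057) or without animal 2 (0.053), 3 (0.052) or 7 (0.060), nor with those 4 animals (0.085).

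**Figure D1:**
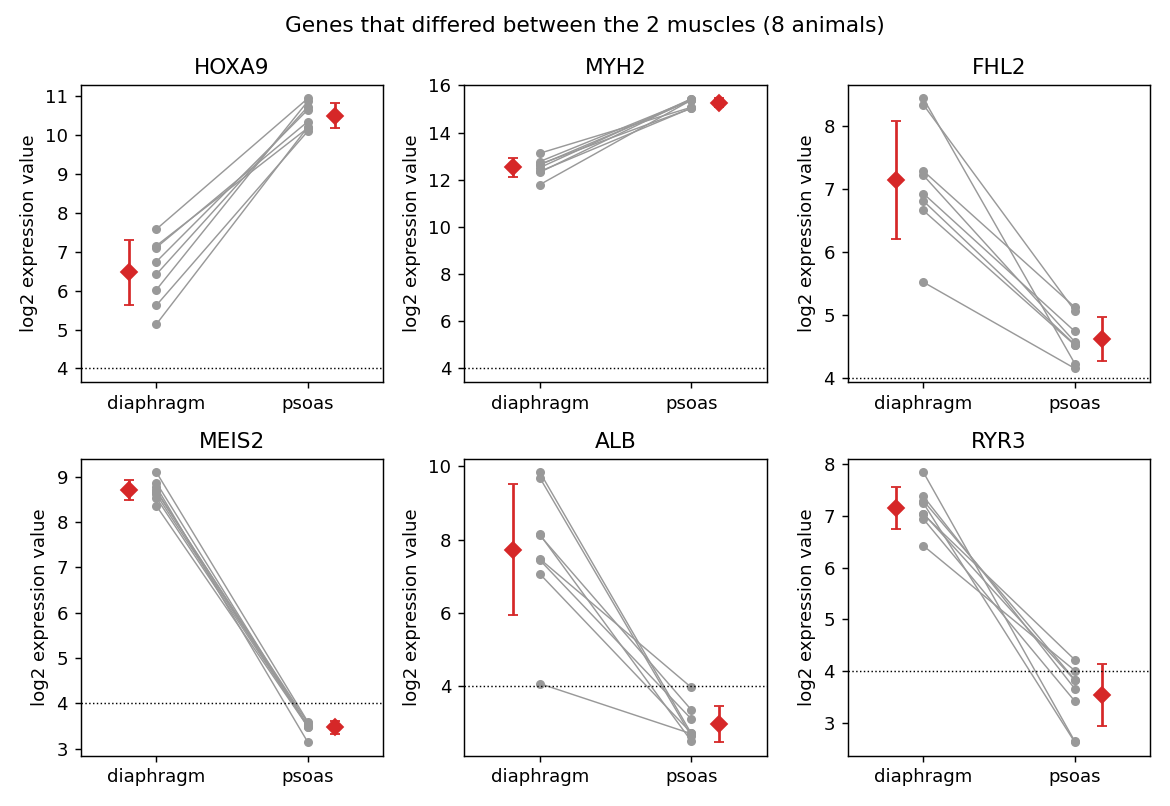
Log2 expression value of 6 genes in the diaphragm and psoas of each of 8 animals (grey points joined by animal), with the mean and SD of each muscle as a red diamond and the filter level of 4 as a dotted line. HOXA9 and MYH2 were higher in psoas, and FHL2, MEIS2, ALB and RYR3 higher in diaphragm, in 8 of 8 animals.

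Genes of fast fibres and of glycolysis were higher in psoas. Of 9 fast fibre genes tested, 6 rose and none fell in psoas (7 rose adjusted over the list alone). They were led by MYH2 and by ATP2A1, the calcium pump of fast fibres (log2 difference 0.98 ± 0.12 SE, adjusted p = 8.3e-05), TPM1 (0.34) and the fast troponin TNNT3 (0.33). Of 15 glycolysis and glycogen genes, 10 rose (12 adjusted over the list alone), among them PGAM2, phosphoglycerate mutase of muscle (0.53 ± 0.06 SE, adjusted p = 3.6e-05), GPI (0.70), PGK1 (0.57) and TPI1 (0.43). Camera gave adjusted p = 2.1e-04 for the fast fibre list and 3.5e-05 for glycolysis. Neither call held with an estimated correlation (adjusted p = 0.22 for both).

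Several genes of slow fibres and of fatty acid oxidation, and a few of mitochondrial respiration, were lower in psoas. Of 10 slow fibre genes, 6 fell and none rose (8 fell and 1 rose adjusted over the list alone), including TPM3 (-0.64 ± 0.14 SE), the calsequestrin CASQ2 (-1.48 ± 0.38), the slow calcium pump ATP2A2 (-0.28) and the slow troponin TNNI1 (-0.33). Of 23 fatty acid oxidation genes, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with HADH (-0.48), ACADL (-0.92), DECR1 (-0.51) and lipoprotein lipase LPL (-0.90) of smallest p. Of 37 oxidative phosphorylation genes, 6 fell, none rose and 31 were not called (1 fell adjusted over the list alone). The 6 were COX6A1 (-0.45), NDUFA1 (-0.24), NDUFS1 (-0.39), NDUFS7 (-0.40), COX6C (-0.18) and COX5B (-0.20). Camera gave adjusted p = 0.0044 for slow fibre, 8.3e-04 for fatty acid oxidation and 8.9e-04 for oxidative phosphorylation. With an estimated correlation the adjusted p was 0.49, 0.49 and 0.54, and fry gave 0.0925 for oxidative phosphorylation.

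Many markers of vessels, immune cells and matrix, and a few of fat and fibroblasts, were also higher in diaphragm. Of 9 endothelial markers, 8 were higher in diaphragm and none in psoas, with PECAM1 at -0.88 ± 0.14 (log2 difference ± SE), CDH5 at -0.70, ESAM at -0.52 and VWF at -0.83. Of 11 immune markers, 7 were higher in diaphragm (9 adjusted over the list alone), among them the MHC class II genes SLA-DQB1 (-0.69), SLA-DRB1 (-0.74) and SLA-DQA1 (-0.97) and their invariant chain CD74 (-0.83). Of 18 extracellular matrix genes, 10 were higher in diaphragm and 1 in psoas (14 and 1 adjusted over the list alone). LOX, which crosslinks collagen (-1.31), DCN (-0.66), SPARC (-0.45) and FBN1 (-0.71) were higher in diaphragm, and COL3A1 was higher in psoas (0.45 ± 0.11 SE). Of 8 adipocyte and lipogenesis genes, 3 were higher in diaphragm, namely FABP4 (-1.31), ELOVL6 (-1.25) and CFD (-0.55), and of 7 fibroblast markers 3, namely DPT (-0.80), GSN (-0.39) and CD34 (-0.32). Camera gave adjusted p = 2.3e-05 for endothelial, 4.1e-05 for immune, 6.0e-05 for matrix, 0.0057 for adipocyte and 0.046 for fibroblast genes. With an estimated correlation the adjusted p was 0.22 for endothelial, immune and adipocyte genes and 0.33 for matrix and fibroblast genes.

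Of 14 hepatocyte markers on the array 7 were tested, and all 7 were higher in diaphragm (7 adjusted over the list alone). Among these, 5 lay below 4 on every psoas array and passed the filter through diaphragm alone. Their direction therefore follows from the filter. ALB was at least 13.3-fold, FGB (fibrinogen beta) at least 6.82-fold, HP (haptoglobin) at least 3.41-fold, APOC3 at least 2.79-fold and TF (transferrin) at least 1.03-fold higher, with psoas below 4 on every array. FGG (psoas mean 3.59, below 4) and APOA1 differed by -1.36 and -0.93. The list median was -2.49, and -1.48 with the 5 genes below 4 in psoas at their bound. Camera gave adjusted p = 3.5e-05 and, with an estimated correlation, adjusted p = 0.22. Diaphragm ALB ranged from 4.07 in animal 3 to 9.84 in animal 8, and psoas ALB from 2.50 to 3.97. The mean of the 7 genes in diaphragm lay between 3.64 in animal 3 and 7.93 in animal 8.

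**Figure D2:**
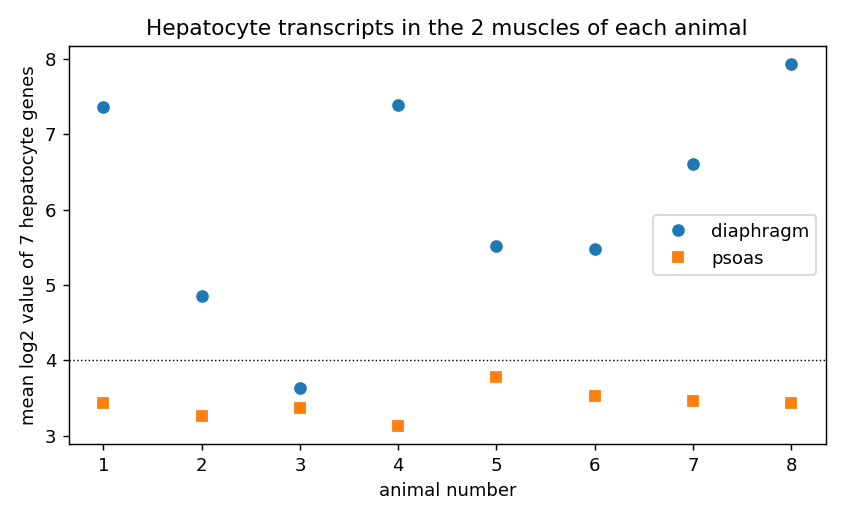
Mean log2 expression value of the 7 tested hepatocyte genes in the diaphragm (circles) and psoas (squares) of each of 8 animals (1 array per muscle and animal), with the filter level of 4 as a dotted line. The diaphragm mean ranged from 3.64 to 7.93 and was above the psoas mean in 8 of 8 animals.

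Of 5 axial patterning genes tested, HOXA9, HOXD8 and HOXD10 (1.10 ± 0.20 SE) were higher in psoas and HOXA3 was higher in diaphragm (-0.49 ± 0.13). The list as a whole did not pass camera (adjusted p = 0.099). Among growth and myogenic genes, 2 of 14 were higher in psoas, MSTN (myostatin, an inhibitor of muscle growth, 0.89) and GHR (the growth hormone receptor, 0.44), and 3 were higher in diaphragm, IGFBP5 (-1.37), IGFBP6 (-0.71) and IGF2 (-0.49). S100A1, a calcium sensor of striated muscle, was higher in diaphragm (-1.27) and RYR1, the main release channel of skeletal muscle, in psoas (0.25), as 2 of 5 calcium handling genes. Of 8 cholesterol synthesis genes, 3 were higher in psoas, FDPS (0.65), CYP51 (0.62) and SREBF2 (0.44). Of 7 smooth muscle markers, CNN1 was higher in psoas and RGS5 in diaphragm (-0.71). MBP, a myelin gene, was higher in diaphragm (-1.003) as 1 of 2 Schwann cell and nerve markers. In the tricarboxylic acid cycle IDH3A was higher in psoas (0.52) and MDH2 (-0.42) and SDHA (-0.33) in diaphragm, out of 19. Of 16 protein breakdown genes, KLF15 (0.48) and FOXO1 (0.34) were higher in psoas and GABARAPL1 in diaphragm (-0.43). GADD45A (-0.99) was higher in diaphragm and GADD45B (0.43) in psoas among 19 immediate early and stress genes, and SAT1 (-0.94) in diaphragm and ODC1 (0.67) in psoas among 8 sex steroid response genes. EIF1AX (0.26) and USP9X (0.25) were higher in psoas out of 7 X-linked genes. None of 5 circadian genes was called, with DBP at -0.36, RORA at 0.35 and PER1 at 0.32, although these 3 passed with the animal as a block (adjusted p = 0.040, 0.025 and 0.016). No Y-linked (1 tested), mesothelial (1) or erythrocyte (2) marker was called. With the animal as a block, 4 of the growth and 3 of the protein breakdown genes were higher in psoas. Higher in diaphragm were then 2 of the protein breakdown, 2 of the smooth muscle, 2 of the Schwann cell and 3 of the tricarboxylic acid cycle genes. The lists of this paragraph that camera could test had adjusted p from 0.084 to 0.91, while fry called axial patterning (adjusted p = 4.8e-05), X-linked (2.0e-04) and cholesterol synthesis genes (0.0104). The sign of the test, the median and the mean differed within the calcium handling, protein breakdown, sex steroid and smooth muscle lists.

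**Figure D3:**
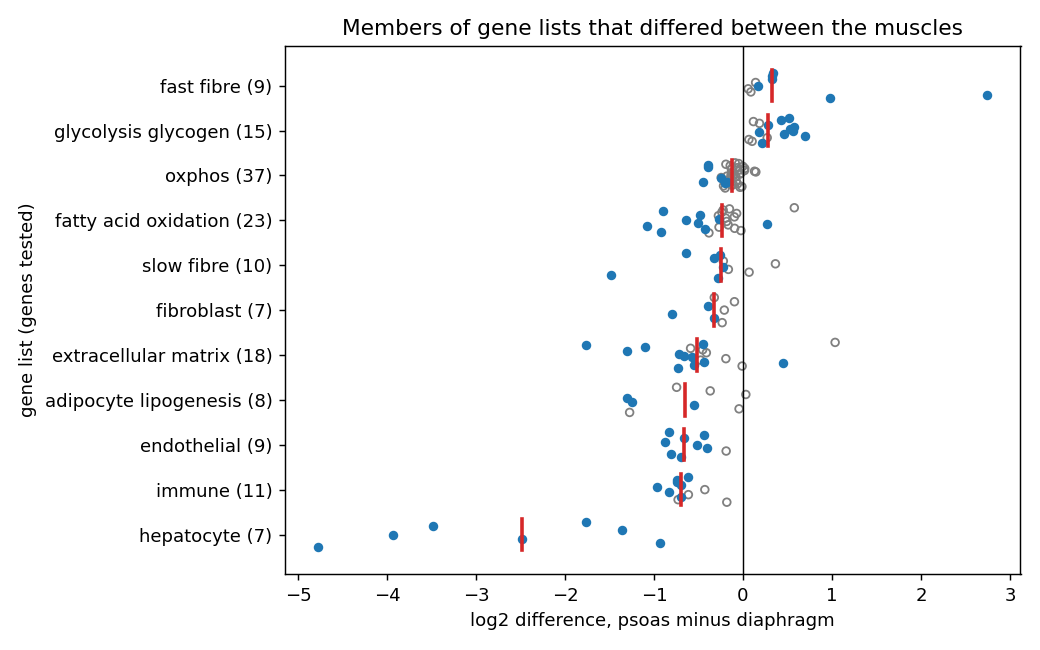
Log2 difference, psoas minus diaphragm, of each tested gene (points, filled where the adjusted p was under 0.05) in the 11 gene lists that passed camera with a preset correlation, with the list median as a red line and the number of genes tested in brackets. Fast fibre and glycolysis genes lie to the right of 0 and the other 9 lists mostly to the left.

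Of the signs of RNA quality, the actin and GAPDH controls leaned the same way as the groups higher in diaphragm. The GAPDH 3' minus 5' difference was lower in psoas in every animal but animal 7, by small amounts in some. The EF1a difference between the muscles did not clearly lean to 1 side. The 3' minus 5' difference of the actin control probe sets was 3.81 ± 0.45 in diaphragm and 3.45 ± 0.25 in psoas (log2, SD, n = 8 each), with psoas lower in 6 of 8 animals (exact sign-flip permutation test, two-sided, p = 0.094). For actin, the diaphragm arrays of animals 1, 2, 3 and 5 had 4.07 to 4.33 and those of animals 4, 6, 7 and 8 had 3.35 to 3.49. The same diaphragm arrays of animals 1, 2, 3 and 5 were also higher for GAPDH (-0.045 to 0.078 against -0.234 to -0.069). For EF1a they had 0.906 to 1.27 against 0.697 to 0.901. With animals 4, 6, 7 and 8 alone, an alternative chosen after seeing the data, 405 probe sets were called. The 70 choices of 4 animals gave 157 to 2264 calls, with a median of 623.5. In those 4 animals 5 of 7 hepatocyte markers, 2 of 9 endothelial markers and 2 of 18 matrix genes were still called higher in diaphragm, with list medians of -3.02, -0.65 and -0.56. Of the fast fibre genes 2 of 9 and of the glycolysis genes 3 of 15 were called higher in psoas (medians 0.27 and 0.33). None of 11 immune markers was called by limma there, with a median of -0.70.

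Of the 5 genes with a symbol that were called between males and females, 3 are annotated to the X or Y chromosome. EIF1AY, a translation factor gene of the Y chromosome, was at least 49.6-fold higher in males, at 9.63 ± 0.10 against 2.83 ± 0.23 (log2, SD, n = 4 animals each, adjusted p = 6.2e-08), and every female array lay below 4. KDM6A, an X-linked histone demethylase gene, was 2.21-fold higher in females (log2 difference 1.15 ± 0.10 SE, adjusted p = 0.0037). DKK2 was higher in females (1.28 ± 0.16 SE, adjusted p = 0.033, with the opposite sign at its other probe set) and YEATS4, a chromatin reader, higher in males (-0.76 ± 0.08, adjusted p = 0.012). The probe set annotated to X-linked ZFX was higher in males (-1.60 ± 0.20, adjusted p = 0.033), with a female mean of 3.83, below 4. ZFX has a similar Y-linked copy, ZFY, so that its identity is uncertain.

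In all, 21 probe sets were called, 11 higher in females and 10 higher in males, and the 5 genes above were those with a symbol. Of the other 16, whose chromosomes were not known here, those with the largest bounds were Ssc.16426.1.S1_at (at least 67.6-fold) and Ssc.7473.1.A1_at (at least 53.4-fold) in males, and Ssc.31029.1.A1_at (at least 50.3-fold) and Ssc.13426.1.A1_at (at least 47.8-fold) in females. Every array of the other sex lay below 4 for these 4, which were chosen after their values were seen. With animals as a block over all 16 arrays 39 probe sets were called, 16 of them among the 21. In this comparison over both muscles, KDM6A and EIF1AY passed under every alternative. DKK2, YEATS4 and ZFX did not pass with the block (adjusted p = 0.23, 0.17 and 0.079), and each failed in 6 or 7 of the 8 fits that left out an animal. Without animal 2 or animal 3, 13 probe sets were called.

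**Figure D4:**
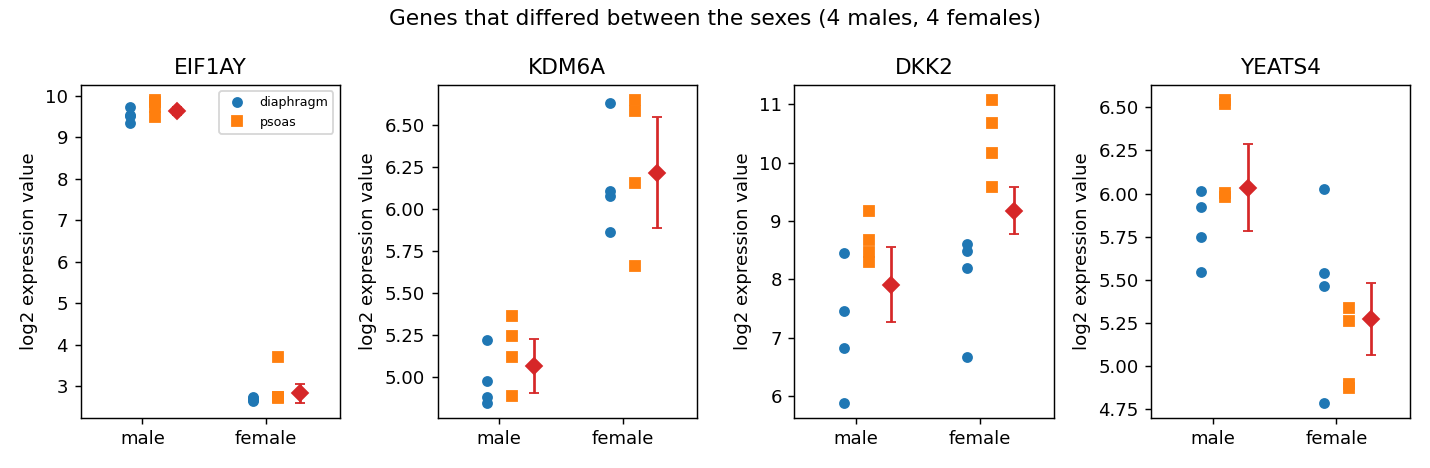
Log2 expression value of 4 genes in diaphragm (circles) and psoas (squares) of 4 males and 4 females, with the mean and SD over animal means as a red diamond. EIF1AY was near 9.63 in males and 2.83 in females, and KDM6A and DKK2 were higher and YEATS4 lower in females.

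No gene of the metabolic lists was called between the sexes. Camera gave a lower oxidative phosphorylation list in females (adjusted p = 0.0014, but adjusted p = 0.68 with an estimated correlation, 0 of 37 genes called and 0 adjusted over the list alone), with ATP5L at -0.26, COX7A2 at -0.45, ATP5G3 at -0.27 and NDUFB10 at -0.19. It gave higher lists of X-linked genes (0.0014, KDM6A higher and ZFX lower of 7, and 4 and 1 adjusted over the list alone), calcium handling (0.010, 0 of 5, 3 adjusted over the list alone), fast fibre (0.015, 0 of 9) and glycolysis genes (0.024, 0 of 15), the last 2 with 0 adjusted over the list alone. With an estimated correlation the adjusted p of these 4 was 0.21, 0.25, 0.57 and 0.57, so that none of the 5 lists passed. USP9X (0.50) and EIF1AX (0.40) had the next smallest p of the X-linked genes, and HRC (0.29), RYR1 (0.26) and S100A1 (0.66) those of calcium handling. ATP2A1 (0.38) and GPI (0.20) had the smallest p of the fast fibre and glycolysis lists. USP9X passed with the animal block (adjusted p = 0.0049). The other 17 testable lists had adjusted p from 0.056 to 0.76, with DNAJA1 (-0.72) as their 1 gene past the threshold adjusted over its list alone. In the lists too small for camera, EIF1AY and MBP (0.47) passed adjusted over the list alone. Of those with fewer than 3 tested genes, only the Y-linked list had a call.

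Within diaphragm 14 probe sets differed between the sexes and within psoas 11. EIF1AY passed in both muscles, at least 46.2-fold higher in males in diaphragm and at least 53.2-fold in psoas. KDM6A passed in diaphragm (1.19, adjusted p = 0.041) and was 1.11 in psoas (adjusted p = 0.077). Its call in diaphragm was lost in 7 fits that left out 1 animal. It was also lost with no filter, without the feeding covariate and with the grouping of animals 1, 2, 3 and 5 as a covariate. In psoas YEATS4 (-1.17), CSE1L (-0.63) and the tubulin TUBB4B (-1.02) had the next smallest p and did not pass, nor did CPT1B, the carnitine transferase of muscle mitochondria (-0.76, adjusted p = 0.064), MCFD2 (-0.60) or ATP2A1 (0.55) in diaphragm. No probe set passed in the test of whether the muscle difference depended on sex (limma, 1161 at an unadjusted p under 0.05, where chance gives 573). The genes of smallest p were SLC26A6 (-1.24), IGFBP6 (-1.40), LOC100525232 (0.77), PARP8 (1.08) and LMNA (-0.96), each with adjusted p = 0.34.

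No probe set passed the threshold between the feeding levels. HOXA3 (log2 difference, restricted minus high, 0.82 ± 0.14 SE), the iron-inserting enzyme FECH of heme synthesis (0.43 ± 0.08), HNRNPU (0.57), FBXL4 (0.84) and INO80C (0.40) had the smallest p among genes higher under restriction. POLR2H, a subunit of RNA polymerase (-0.65 ± 0.09 SE), the nesfatin precursor NUCB2 (-0.61 ± 0.10), AP2M1 (-0.75), SLC31A2 (-0.95) and the small heat shock protein HSPB7 (-0.63) had the smallest p among genes lower under restriction. None of the 10 was past the threshold (adjusted p = 0.28 for each, n = 4 animals per level). By limma 1451 probe sets had an unadjusted p under 0.05 where chance gives 573, and the fit with animals as a block called 0 as well, with 1659 at an unadjusted p under 0.05. The count of 1451 was 890 without animal 2, 924 without animal 4 and 2022 without animal 1, and 1 probe set was called without animal 3 or without animal 6.

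Camera gave higher fast fibre (adjusted p = 0.0084), circadian (0.0084), glycolysis (0.017) and fatty acid oxidation (0.024) lists under restriction, with 0 genes called and 0 adjusted over the list alone in each. With an estimated correlation the adjusted p was 0.83, 0.40, 0.83 and 0.83, so that no call held. The members of smallest p were MYH2 (0.24), TPM1 (0.15) and ATP2A1 (0.16) of 9 fast fibre genes, the clock output gene DBP (0.61) with CRY2 (0.34) and PER1 (0.82) of 5 circadian genes, FBP2 (0.68), GPI (0.28) and TPI1 (0.24) of 15 glycolysis genes, and ANGPTL4 (0.84) and DECR1 (0.27) of 23 fatty acid oxidation genes. The other 18 testable lists had adjusted p from 0.082 to 0.73, and no gene of any list was called over all probe sets. Adjusted over the list alone, 9 genes of those lists passed: the lipogenic desaturase SCD (-1.19), AGPAT2 (-0.42), IGFBP6 (-0.69), DNAJA1 (-0.72) and ODC1 (-0.86), lower under restriction, and HOXA3 (0.82), KDM6A (0.40), CNN1 (0.56) and SMTN (0.46), higher. Each had adjusted p from 0.28 to 0.30 over all probe sets. SCD had a mean log2 value of 4.42 over all arrays, near the filter level of 4.

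Within diaphragm the smallest p among genes with a symbol belonged to PDK3 (-0.69), MAP1LC3A (-0.76), MRPS12 (-0.75), EPAS1 (-0.71) and complement C3 (-1.62), each with adjusted p = 0.47 (0 called by limma, 1101 at an unadjusted p under 0.05, and 655, 686 and 1740 without animals 2, 4 and 1, with 2 called without animal 3). Within psoas it belonged to RILPL2 (at least 1.499-fold lower under restriction, adjusted p = 0.17), NUCB2 (-0.83), HOXA3 (0.82), FECH (0.59) and EPHX1 (0.68), the last 4 with adjusted p = 0.31 (0 called by limma, 1291 at an unadjusted p under 0.05 and 843 without animal 2, with 1 called without animal 3). No probe set passed for a dependence of the muscle difference on feeding level (limma, 696 at an unadjusted p under 0.05). There PLBD1 (1.07, adjusted p = 0.41), OCA2 (-1.62, mean over all arrays 3.32, below 4), CTH (1.11), MLF1 (0.91) and the topoisomerase TOP2A (1.09, mean over all arrays 3.47, below 4) had the smallest p. None passed for a dependence of the feeding difference on sex (limma, 396 at an unadjusted p under 0.05, but 849 without animal 4 and 257 without animal 2, with 1 called without animal 2), where CYP3A39 (1.67), TAPBP (0.87), ZFP36 (0.91), RETREG1 (1.68) and COX7A2 (0.82) had the smallest p, each with adjusted p = 0.9996. With 2 animals per combination this last fit had 4 residual degrees of freedom. The mean of CYP3A39 over all arrays was 3.9996, near the filter level of 4.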

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

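The tests of hepatocyte, endothelial, immune and smooth muscle markers and those with the actin difference were chosen after the results were seen, and the counts over splits of the samples before. Of 95 groups of named genes and array measures, 4 held 1 sample far from the others, where chance gives about 4.75. Psoas PEG10 in animal 1 was 7.49 against 5.83 in the nearest other animal (gap over range 0.663). Psoas MEIS2 in animal 2 was 3.14 against 3.48 (0.755), below the filter level in every psoas array. The animal mean of EIF1AY in female 6 was 3.17 against 2.74 (0.914), and that of HNRNPU in animal 1 on the high level was 5.56 against 5.82 (0.840).

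For 4 unnamed probe sets the sex difference differed between the muscles by limma, with adjustment over only the 21 called between the sexes. Over all 11467 tested probe sets none passed in that fit (smallest adjusted p = 0.34), so that the 4 rest on the narrower adjustment. The female minus male difference in psoas minus that in diaphragm was -0.83 for Ssc.21512.1.A1_at, 0.59 for Ssc.6667.1.A1_at, 0.69 for Ssc.27304.1.S1_at and -2.95 for Ssc.3771.1.A1_at. The last was lower in females in psoas (-2.92) and differed by 0.03 in diaphragm (adjusted p = 0.036 over the 21). For the other 3 every array of 1 sex lay below 4, so that their values rest on differences against background and are not read as a dependence on the muscle.

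Hepatocyte transcripts were higher in diaphragm than in psoas. In an acute-phase response of the animals haptoglobin and fibrinogen rise while albumin and transferrin fall. Over the 8 diaphragm arrays the mean of HP, FGB and FGG instead went up with that of ALB and TF (r = 0.898, exact permutation p = 0.0027, adjusted 0.0054 over 2 relations). The rank correlation was rho = 0.929 (exact permutation p = 0.0022), and r was 0.966 without the 2 farthest arrays. Liver RNA varying in amount between the 8 diaphragm arrays would move them all together. This relation therefore cannot decide on an acute-phase response. Most of the 7 tested markers moved together over those arrays (median pairwise r = 0.725, lowest pair -0.0527, permutation p = 1e-04, the smallest 10000 resamples can give), as liver tissue or its RNA in the samples would give, and of the 7 only APOA1 had a psoas mean at or above 4 (7.002). The mean of 7 further listed markers left out by the filter followed theirs (r = 0.713, exact permutation p = 0.034, adjusted 0.034; rho = 0.905, exact permutation p = 0.0046; r = 0.768 without the 2 farthest). AMBP, APOH and AHSG among them reached 5.002, 4.57 and 4.43 in diaphragm and at most 2.01, 2.46 and 2.63 in psoas, yet none of the 7 had a diaphragm mean at or above 4, and TTR, APOA2 and HPX, abundant in liver, reached at most 3.08, 2.73 and 2.68 while ALB reached 9.84, so that a share of liver and weak probe sets cannot be told apart for them. Liver material may be the source, as a hypothesis that no test here set against expression by the diaphragm itself, which stays open as untested.

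Endothelial and immune markers were higher in diaphragm than in psoas. A lower share of muscle fibres in the diaphragm samples could raise smooth muscle markers as well. Their median did lie toward diaphragm (-0.18 ± 0.19, SD, 8 of 8 animals, exact sign-flip permutation p = 0.0078), with CNN1 the other way. The endothelial median lay beyond the smooth muscle one by -0.39 ± 0.19 (psoas minus diaphragm, log2, SD, 8 of 8 animals, exact sign-flip permutation p = 0.0078, the smallest 8 animals can give). Tissue in place of fibres need not hold vessels and smooth muscle in equal amounts, so that this cannot decide on a lower fibre share. RNA quality, as the actin 3' minus 5' difference measures it, is argued against as the whole cause. Animals 4, 6, 7 and 8, whose diaphragm arrays lacked the high actin difference, showed 104% of the shift (-0.66 ± 0.33 against -0.64 ± 0.27 in all 8, SD). Other measures of RNA quality were not tested in this way. A lower fibre share as the whole or a part of the cause stays open, and a difference between the muscles themselves and differences in tissue sampling stay open as untested.

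Feeding gave many small unadjusted p-values with no call (1451 at an unadjusted p under 0.05, 890 without animal 2 and 924 without animal 4). Of 34 splits of the 8 animals, the real one among them, 2 gave at least as many probe sets. The highest other gave 1710, so chance was not excluded. That split set animals 1, 2, 3 and 5 against the rest, the animals whose diaphragm arrays had the high actin difference. Animals 2, 3 and 5 were restricted and animal 1 was not. Animals 1, 2 and 3 were males and animal 5 a female. The grouping thus overlaps with feeding and with sex, and a fit with it as a covariate can take up a part of either. Its count may point to a structure of the samples or to a part of the feeding difference. With the actin difference as a covariate 1318 were at an unadjusted p under 0.05, above the 573 of chance. This measure alone may therefore not account for the excess, and a feeding effect too small for 4 animals stays open.

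For the other fits as well, each count of splits includes the real one. Between muscles 1 of 100 splits of the 16 arrays gave 3094 calls (highest other 423). Of 100 splits that part every animal's arrays, 1 did (highest other 918, which exchanged the muscles of 1 animal), so chance was excluded. For sex, 1 of 34 splits reached 21 calls (highest other 6), and in psoas 1 of 34 reached 11 (highest other 5). Probe sets such as EIF1AY, with every array of 1 sex below 4, part cleanly only by the real split. They favoured that split from the outset, so that these counts cannot decide on chance. The counts also say nothing on other calls such as DKK2, YEATS4 and ZFX. In diaphragm 2 of 34 splits reached 14 calls, so chance was not excluded for the count, which says nothing against single calls such as EIF1AY (adjusted p = 3.9e-08). The highest other, 56, was again animals 1, 2, 3 and 5 against the rest, a grouping that shares males 1, 2 and 3 with the real split. With that grouping as a covariate 11 probe sets were called in diaphragm, 10 of them among the 14. Counts at an unadjusted p under 0.05 did not exclude chance for feeding in diaphragm (5 of 34 splits reached 1101, highest other 2308, the same grouping, and 823 with it as a covariate; 655, 686 and 1740 without animals 2, 4 and 1), for feeding in psoas (3 of 34 reached 1291, highest other 1614; 843 without animal 2), for the muscle difference by sex (2 of 34 reached 1161, highest other 1170) or by feeding (8 of 34 reached 696, highest other 1114).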

How the results depend on the processing

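Fits with the actin difference, with the grouping of animals 1, 2, 3 and 5, or with animals 4, 6, 7 and 8 alone were chosen after seeing the data. Between muscles the count lay between 2162 and 3836 under every alternative except animals 4, 6, 7 and 8 only (405, with fewer arrays in the fit). It was 2162 to 2906 without 1 animal and 3836 with the replicate block, which changed the calls of 6 named list genes (DBP, RORA, PER1, FBXO32, PDGFRB and SDHD, all gained) and no list call. Beyond the named genes the block gave 13 in place of 10 matrix genes, 9 in place of 7 immune markers and 10 in place of 8 fatty acid oxidation genes lower in psoas. It also gave 7 in place of 6 oxidative phosphorylation genes and 4 in place of 3 adipocyte genes lower. Higher in psoas were 9 in place of 10 glycolysis genes and 2 in place of 1 fatty acid oxidation genes. For sex the replicate block gave 39, with USP9X gained and DKK2, YEATS4 and ZFX lost among the named genes, and 13 to 23 were called without 1 animal. For feeding 0 or 1 were called without 1 animal (1 without animal 3 or 6) and 0 with the replicate block. In diaphragm feeding gave 1 with no filter, 1 with the stricter filter, 1 with array weights, 2 without the sex covariate and 0 to 2 without 1 animal (2 without animal 3). In psoas it gave 2 with no filter and 0 or 1 without 1 animal (1 without animal 3). The dependence of feeding on sex gave 0 or 1 without 1 animal (1 without animal 2). The cause was not tested for these, beyond fewer samples where animals were left out. Of 87 called genes named between muscles, 53 lost the call with 4 animals, 17 in at least 1 fit without 1 animal, 13 with no filter and 8 with the actin covariate. Direction changed for CRY2, at -0.0318 without animal 7 within a range of -0.0318 to 0.0989 without 1 animal, and for NR3C1 with animals 4, 6, 7 and 8 only (-0.0316), neither called. All list calls were lost with an estimated correlation (11 of 11, 5 of 5 and 4 of 4). With no filter 12 muscle, 8 sex and 2 feeding lists were called. With the mean of a gene's probe sets 4 of 5 sex lists stayed, and the muscle and feeding list calls did not change. Fry called 13 muscle lists, 10 of the 11 and axial patterning, cholesterol synthesis and X-linked genes, and kept 1 of 5 sex lists and 0 of 4 feeding lists. Low signal limits genes near the level of 4.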
